A study of Homo sapiens with 3 samples.

How the data were processed

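RNA sequencing was carried out on 3 cell lines derived from HaCaT, a spontaneously immortalised human keratinocyte line. Per the labels, HaCaT cells were first made to express an oncogenic form of HRAS and were then transduced with an empty vector, with wild-type THG-1 (the protein encoded by TSC22D4) or with THG-1 S264A, in which 1 serine is replaced by alanine. Total RNA was extracted with Trizol from cells grown in DMEM with fetal bovine serum and was sequenced on a NextSeq500, per the labels. Each line was represented by 1 library. Library selection (poly(A) or rRNA depletion) and strandedness are not given in the sources used here.

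The deposited table holds 57773 rows with gene symbols and, for each library, 2 columns. Per the file headers, the first column holds expression values, which are RPKM (read counts divided by gene length and by library depth) computed by the authors library by library. The second column, headed as normalised expression values, was tested on the values. It is RPKM quantile-normalised across the 3 libraries by the authors, since its sorted values are the same in every library and equal the means of the sorted RPKM. The RPKM columns were used for the main results and the quantile-normalised RPKM columns for an alternative. Genome build hg19 is named in the submitters' processing notes. The aligner, the counting program and the annotation are not given in the sources used here. The table carries no coordinates, and the annotation at hand (GENCODE release 29) belongs to another build, so that no positions are printed.

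The RPKM values moved in steps that correspond to whole reads over gene length and library depth. The depth of each library was therefore taken from genes with 1 exon and a known length, among which 1 read was the commonest count, and the whole reads of each row from the lengths at which the values of all 3 libraries came out whole within 0.001 reads. Lengths from GENCODE release 29 (union of exons) chose among such lengths, and served only as lengths. Whole reads were recovered for 25997 of the 25998 rows above 0, or 99.996%. Among rows at or above 1 RPKM, 91.9% had a length that was either that of GENCODE or chosen by it. Among rows above 0, the GENCODE length itself fitted for 44.4%. For 30.1% it did not, and the multiple of the smallest fitting length nearest to it was used. For the other rows the smallest length that fitted was used, which can understate the reads and so widen the intervals. On simulated values with known reads, all 3 depths were found exactly, and the reads of 5000 of 5000 rows were recovered with the length known and of 4482 (89.6%) without it. The depths were 32055052 reads for the empty-vector library, 12733479 for wild-type THG-1 and 14022885 for S264A. At these depths a gene of 1 kb with 1 read stands at 0.0312, 0.0785 and 0.0713 RPKM. The recovered reads were used for intervals, for simulations of counting noise and for thinning, and no test on counts was run.

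With 1 library per group there is no spread between replicates, so that no p-value is given for any gene, list or comparison, and a difference between libraries cannot be separated from variation between cultures. Genes were compared by size. The fold change was log2((RPKM a + 1)/(RPKM b + 1)), which understates the change of low genes. Genes at or above 1 RPKM in at least 1 of the 2 libraries entered, and those with a fold of at least 2 on this scale were counted as higher or lower. Where a symbol had several rows (234 of 55773 symbols), the row with the highest mean was taken. A fold printed for a single gene is the plain ratio of RPKM values, with an exact Clopper-Pearson 95% interval from the reads. Reads are not independent molecules, and these intervals and the floors of 3 reads used for a library at 0 cover counting error only. Counting noise alone was simulated 100 times by drawing the reads of each gene at its pooled rate and the real depths. In reads simulated for wild type against empty vector over 11678 genes, with 50 genes of at least 2 RPKM at each fold, the rule called 2% of those changed 2-fold, 92% of those changed 3-fold and 98% of those changed 4-fold, and 0.296% of the unchanged genes. The corresponding shares were 6%, 88% and 98% for S264A against empty vector over 11680 genes, and 8%, 100% and 94% for S264A against wild type over 11747 genes.

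Before the data were examined, 22 gene lists, 4 lists of markers of other cell types, the comparisons and the rule for named genes were fixed. The lists covered NF-kB targets, the IL-1 family and its signalling, chemokines and cytokines, antimicrobial and stress genes, type I interferon-stimulated genes, RAS-MAPK output, the cell cycle, basal keratinocyte genes, suprabasal differentiation, mesenchymal transition, epithelial junctions, extracellular proteases, TGF-beta targets, p53 targets, NRF2 antioxidant genes, hypoxia and glycolysis, the unfolded protein and integrated stress response, sterol synthesis, the TSC22 family and its partners, squamous stem and progenitor genes, and, for comparison, ribosomal protein and respiratory chain genes. Lists could share members, above all the NF-kB list and the chemokine and cytokine list, so that they are not independent results. The members of a list at or above 1 RPKM in at least 1 library were summarised by their median log2 fold change. Members at least 2-fold higher or lower were counted among those at or above 1 RPKM in the compared pair, so that some counts are out of fewer members than the median. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. A list outside the 2.5 to 97.5 percentiles is called above or below its random lists, as a description of these libraries. In the simulated reads for wild type against empty vector, with fewer random lists per list, 9 of 200 unchanged lists of 25 genes (4.5%) were outside that range, and all 200 lists raised 1.5-fold were above it. The simulated lists held genes drawn at random with counting noise alone. They do not show how often lists of genes that vary together fall outside the range. Named genes were the 12 highest and 12 lowest against the empty vector in each THG-1 line and the 8 highest and 8 lowest of S264A against wild type, at or above 5 RPKM and leaving out symbols with the prefixes fixed beforehand for small and unnamed RNAs and antisense symbols, which did not cover RNVU1-13. These prefixes also removed MIR143HG, a long noncoding RNA, from the ranking. Up to 4 members per list with the largest changes and a set of 11 preset genes were added.

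Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, scaling of the libraries to an equal median ratio, to an equal upper quartile or to an equal sum, fold thresholds of 1.5 and 4, summed repeated symbols, 10 bins, means in place of medians, and the NF-kB list without IL-1 family members. The upper quartile was taken over the genes above 0 in each library. Such genes were more numerous in the deeper empty-vector library. The factors of this scaling (0.834 for wild type and 0.867 for S264A, relative to empty vector) can therefore carry depth. The quantile-normalised columns, reads thinned to the shallowest depth, and protein-coding genes alone were added after seeing the data. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.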

Results

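Transcript levels were measured by RNA sequencing in HaCaT keratinocytes that express oncogenic HRAS and that carried an empty vector, wild-type THG-1 or THG-1 S264A, with 1 library for each of these 3 lines. THG-1, encoded by TSC22D4, is a member of the TSC22 family of leucine zipper proteins. The title of the series concerns promotion of the IL-1 and NF-kB pathway by THG-1, and the 3 lines allow the effect of wild-type THG-1, that of the S264A form, and the difference between both forms to be examined. The depth was 32055052 reads in the empty-vector library, 12733479 in the wild-type THG-1 library and 14022885 in the S264A library, so that the empty-vector library was 2.52 times as deep as the wild-type library. Rows above 0 numbered 23557, 20992 and 21773 in the same order. There were no replicates, and intervals on single genes cover counting error only.

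TSC22D4 stood at 7.98 RPKM with empty vector, 64.9 RPKM with wild-type THG-1 and 51.1 RPKM with S264A. The ratio to the empty-vector line was 8.14 (95% counting interval 7.57 to 8.76) for wild type and 6.41 (5.95 to 6.91) for S264A, and the S264A line held 0.787 times (0.747 to 0.829) the level of the wild-type line. HRAS was at 23.9, 27.8 and 22.4 RPKM in the same order. Its log2 difference of 0.21 between wild type and empty vector became -0.04 when libraries were scaled to the same upper quartile. ACTB was at 815, 798 and 753 RPKM and GAPDH at 601, 619 and 517 RPKM. The GAPDH difference of 0.04 on the log2 scale between wild type and empty vector became -0.22 with upper-quartile scaling and -0.12 with scaling to an equal sum. The ACTB difference of -0.08 between S264A and wild type became 0.03 with scaling to an equal sum.

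**Figure D1:**
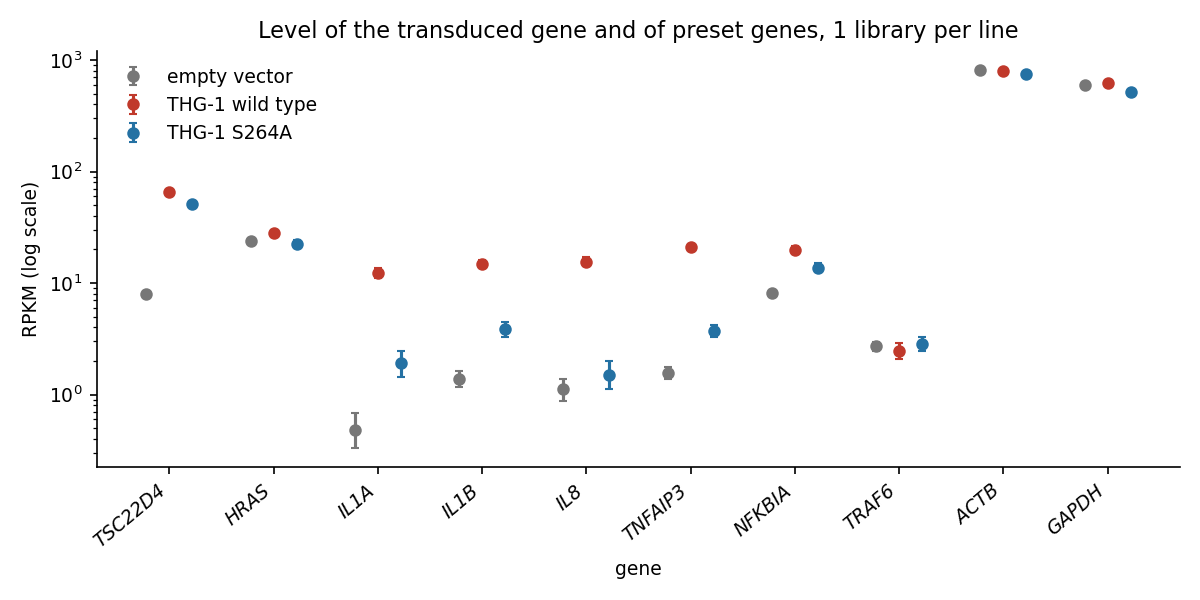
RPKM on a log axis of TSC22D4, HRAS, 6 preset genes of the IL-1 and NF-kB pathway and 2 housekeeping genes in the empty-vector, wild-type THG-1 and THG-1 S264A lines, 1 library each, with bars for the exact Poisson 95% counting interval. TSC22D4 stood at 7.98 RPKM with empty vector and at 64.9 and 51.1 RPKM in the THG-1 lines, while IL1A, IL1B, IL8 and TNFAIP3 were highest with wild-type THG-1.

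The first comparison asked what wild-type THG-1 changed in the presence of oncogenic HRAS. Inflammatory genes were higher in the wild-type THG-1 line. IL1A, which encodes interleukin-1 alpha, was at 0.485 RPKM with empty vector and at 12.3 RPKM with wild-type THG-1, a ratio of 25.5 (17.8 to 37.6). IL1B, which encodes interleukin-1 beta, went from 1.39 to 14.8 RPKM, a ratio of 10.7 (8.85 to 12.9). The neutrophil chemokine gene IL8 (CXCL8) went from 1.11 to 15.5 RPKM, a ratio of 14.0 (11.02 to 17.9). TNFAIP3, which encodes the NF-kB inhibitor A20, was 13.5-fold higher (11.8 to 15.5), and NFKBIA, which encodes the inhibitor IkB-alpha, 2.45-fold higher (2.19 to 2.75). With upper-quartile scaling the log2 difference of NFKBIA went from 1.20 to 0.95, under the 2-fold rule. TRAF6, an adaptor of IL-1 receptor signalling, was at 2.71 and 2.47 RPKM, a ratio of 0.911 with an interval of 0.752 to 1.10. IL6 was near the floor, with 7 reads with empty vector and 2 reads with wild-type THG-1.

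Of the 29 measured members of the NF-kB target list, 18 were at least 2-fold higher in the wild-type line and 0 at least 2-fold lower. The median log2 fold change was 1.47, above all matched random lists (percentile 100). On the scale of log2 RPKM + 1, LIF was the member with the largest change, from 1.91 to 33.4 RPKM, followed by PLAU, which encodes urokinase, from 10.1 to 102 RPKM. In the IL-1 family list 8 of 27 members were at least 2-fold higher, namely IL1A, IL1B, IL1RN, IL1R1, IL1R2, IL1RL1, IL1RL2 and IRAK2. Its median was 0.21, at the 98.8 percentile, and lay inside the random range in the authors' quantile-normalised columns (96.2) and with a filter at 5 RPKM (85.0). Among 14 chemokine and cytokine genes 7 were at least 2-fold higher, including CXCL1 (4.67 to 25.3 RPKM) and CXCL16 (4.88 to 30.6 RPKM), with a median of 1.02 and a percentile of 100. All of these 7 except CXCL16 and CCL22 were also counted among the 18 higher NF-kB targets. The macrophage marker CD68, which epithelial cells also express, was at 0.941 RPKM with empty vector, 5.21 RPKM with wild-type THG-1 and 1.70 RPKM with S264A. The other 9 immune markers stayed below 1 RPKM in every library. In each of the remaining marker lists 1 gene reached 1 RPKM, namely FBLN1 for fibroblasts (3.96, 3.39 and 3.84 RPKM in the same order), MITF for melanocytes (0.600, 1.70 and 0.829 RPKM) and VWF for endothelial cells (0.311, 0.348 and 1.51 RPKM, of 5 markers in the table).

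**Figure D2:**
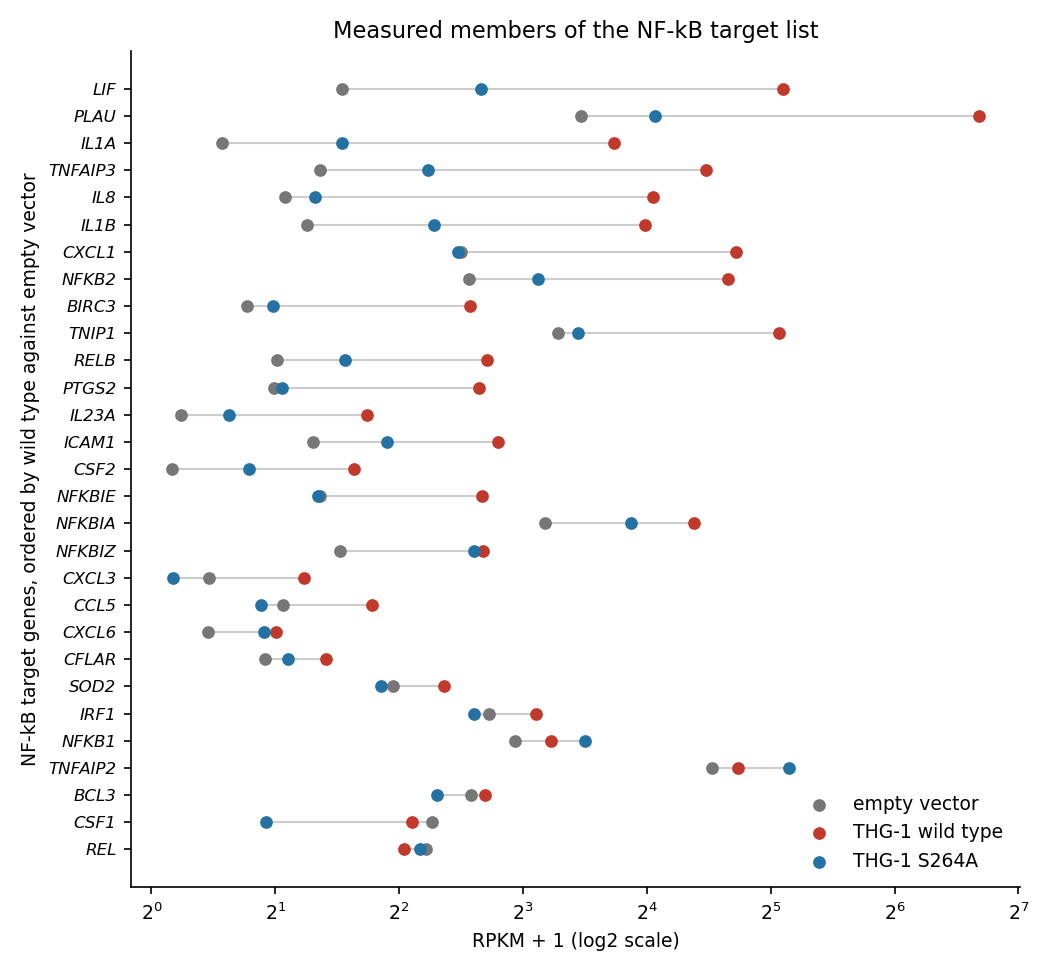
RPKM + 1 on a log2 axis for the 29 measured NF-kB target genes in the 3 lines, 1 library each, with a grey line from the lowest to the highest library and genes ordered by the difference between wild-type THG-1 and empty vector. The wild-type library lay to the right of the empty-vector library for 27 of the 29 genes, and the median log2 fold change of S264A against empty vector was 0.39.

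The epidermal antimicrobial and stress list had the largest median of all lists in this comparison, 2.32 (percentile 100), with 12 of 18 members at least 2-fold higher. The acute-phase genes SAA1 and SAA2 went from 0.122 to 223 RPKM and from 0.140 to 77.0 RPKM. With 3 and 10 reads in the empty-vector library, their ratios were 1819 (622 to 8828) and 550 (298 to 1148). LCN2, which encodes the iron-siderophore-binding protein lipocalin-2, was 60.4-fold higher (49.7 to 74.2), and PI3, which encodes the elastase inhibitor elafin, 170-fold higher (72.0 to 526). Complement C3 was 50.5-fold (45.6 to 56.2), S100A9 29.5-fold (23.3 to 37.7) and S100A7 135-fold (52.1 to 501) higher. SAA1 and SAA2, S100A7 and the SPRR2 genes have close paralogs, and how reads shared between paralogs were counted is not given in the sources used here.

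Interferon-stimulated genes were higher as well, with 16 of 30 members at least 2-fold higher, 2 at least 2-fold lower (HERC5 and IFI44) and a median of 1.03 (percentile 100). OAS2 went from 1.09 to 14.2 RPKM, XAF1 from 0.215 to 6.12 RPKM and IFI6 from 5.73 to 36.5 RPKM. Of 27 RAS-MAPK output genes 9 were at least 2-fold higher and 1 (EPHA4) lower (median 0.85, percentile 100), and DUSP5, which encodes an ERK phosphatase, went from 1.06 to 23.4 RPKM. Of 26 suprabasal differentiation genes compared, 12 were at least 2-fold higher and 1 lower (NOTCH3; median 0.66, percentile 100). The kallikrein proteases KLK5 (63.0-fold, 48.7 to 83.0) and KLK7 (1.85 to 16.8 RPKM) and the cornified envelope genes SPRR2A (60.4-fold, 35.5 to 112) and SPRR2D (0.325 to 15.9 RPKM) led this list. The mesenchymal list had 5 of 13 members at least 2-fold higher (median 0.67, percentile 100), among them SPARC, MYL9, LOXL2 and ITGA5. In the protease list 10 of 25 were higher and 1 lower (median 0.31, percentile 99.6), with SERPINB2 from 13.7 to 248 RPKM and ADAM19 from 2.27 to 29.3 RPKM, and its call was lost without a filter (89.4). Epithelial junction genes (median 0.22, percentile 97.7) and p53 targets (0.20, 98.2) were slightly above their random lists, the former with CLDN4 and GJB2 higher and GJA1 lower, the latter with CDKN1A, GDF15, GADD45A and PLK3 higher. With upper-quartile scaling the medians of the IL-1 family (-0.02), junction (-0.01) and p53 lists (-0.02) turned negative, while their percentiles stayed above the random range. The call on junction genes was lost with means of members (82.2), with 10 bins (97.45) and with a filter at 5 RPKM (95.6).

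Cell cycle genes were lower as a group, with a median of -0.35 (percentile 0) although none of 35 members reached a 2-fold difference. The log2 difference was -0.77 for TOP2A, which encodes a topoisomerase, and -0.91 for the cyclin gene CCNB2. Respiratory chain genes had a median of -0.13 (percentile 0.25). The other 9 lists lay within their random range, between the 32.1 percentile of ribosomal protein genes and the 96.9 percentile of hypoxia and glycolysis genes. They comprised, besides these, basal keratinocyte genes (96.4), the unfolded protein and stress response (91.1), sterol synthesis (89.1), TGF-beta targets (88.7), NRF2 antioxidant genes (85.3), squamous stem and progenitor genes (82.5) and the TSC22 family and its partners (43.9). Of these, hypoxia and glycolysis genes passed the range with a pseudocount of 5 (98.4), a filter at 5 RPKM (98.75) and protein-coding genes alone (98.0). Basal keratinocyte genes passed it without a filter (97.85) and with protein-coding genes alone (97.6), and TGF-beta targets without a filter (99.4). The genes with the lowest values against the empty vector were H19, an imprinted noncoding RNA (14.3 RPKM against 0.0559 RPKM, 2 reads, 255-fold lower, 70.6 to 2111), and the stem cell factor SOX2 (26.6-fold lower, 17.1 to 43.6). LYPD1, CALB1, SH3BGRL, PTPRZ1, SESN3, EPPK1, SMARCA1, CYP1B1, MXRA5 and ALPP followed, between 3.89-fold lower for MXRA5 and 48.3-fold lower for CALB1. The 12 highest genes also held the histone gene HIST1H3C (21.3-fold, 16.9 to 27.1) and the pseudogenes PPIAP22 and RPL18AP3, which share sequence with their parent genes. PPIAP22 had 0 reads with empty vector and 165 with wild-type THG-1, at least 138-fold higher against a floor of 3 reads.

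In all, 543 of 11993 genes were at least 2-fold higher and 185 at least 2-fold lower with wild-type THG-1, against means of 15.1 and 14.7 from counting noise alone. The higher share of changed genes was 74.6%, and 53.8% after upper-quartile scaling (365 higher, 313 lower) and 47.6% after scaling to an equal sum. The median gene lay at -0.22 after upper-quartile scaling and at -0.16 after scaling to an equal sum, against -0.01 in the RPKM as deposited. The upper quartile, taken over genes above 0, can carry the difference in depth.

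The second comparison set S264A against empty vector. The same groups of inflammatory genes stood closer to the empty-vector line. IL1A was at 1.91 RPKM, 3.95-fold above the empty-vector line (2.53 to 6.26), IL1B was 2.78-fold higher (2.21 to 3.51) and TNFAIP3 2.36-fold higher (1.98 to 2.81). NFKBIA was 1.69-fold higher (1.497 to 1.92), and IL8 had a ratio of 1.35 with an interval of 0.928 to 1.96. TRAF6 had a ratio of 1.05 (0.880 to 1.25), and IL6 had 4 reads. On the RPKM + 1 scale used for counts, the log2 differences of IL1A (0.97) and TNFAIP3 (0.87) were under the 2-fold rule. Of 24 NF-kB targets compared, 3 were at least 2-fold higher on that scale (LIF, NFKBIZ and IL1B) and 1 lower (CSF1). The median of all 29 was 0.39 (percentile 100). The IL-1 family list had 2 members at least 2-fold higher, IL1B and the receptor antagonist gene IL1RN, and a median of 0.14 at the 96.2 percentile, inside the random range. With upper-quartile scaling the log2 differences of IL1B (0.87), LIF (0.95), NFKBIZ (0.91) and IL1RN (0.88) were under the 2-fold rule. The IL-1 family list passed the random range with a pseudocount of 5 (99.4), without a filter (98.4) and in the quantile-normalised columns (97.7). Its median turned to -0.03 with upper-quartile scaling (percentile 96.4). Chemokines and cytokines had a median of 0.32 (percentile 98.6), with CXCL16 and LIF higher and CSF1 lower. This call was lost under 5 alternatives, among them no filter (77.4) and upper-quartile scaling (80.8, with a median of -0.03). Interferon-stimulated genes had a median of 0.20 (percentile 99.7), with OAS2 and XAF1 at least 2-fold higher and RSAD2 lower, a call that was lost with means of members (95.4) and with a filter at 5 RPKM (95.9).

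Antimicrobial and suprabasal differentiation genes were higher as groups in S264A than with empty vector. In the antimicrobial list 11 of 15 members compared were at least 2-fold higher, and the median of all 18 measured members was 1.44 (percentile 100). LCN2 was 20.4-fold higher (16.7 to 25.2) and S100A9 14.1-fold higher (11.1 to 18.2), and KRT16 went from 0.256 to 7.27 RPKM. In the suprabasal list 10 of 29 members were at least 2-fold higher and none lower (median 0.80, percentile 100). KRT4, a keratin of mucosal epithelium, went from 4.003 to 68.0 RPKM (17.0-fold, 15.35 to 18.9), KLK5 from 1.13 to 49.2 RPKM (43.4-fold, 33.5 to 57.3), SPRR1A from 1.16 to 11.35 RPKM and involucrin (IVL) from 2.77 to 15.3 RPKM. RAS-MAPK output genes (5 of 26 higher, median 0.39, percentile 100), proteases (6 of 25 higher, 2 lower, median 0.43, percentile 99.99) and junction genes (median 0.19, percentile 99.9) were above their random lists. So were NRF2 antioxidant genes, with 7 of 24 at least 2-fold higher (median 0.25, percentile 99.9), among them NQO1 (17.8 to 52.4 RPKM) and AKR1C3 (1.44 to 7.46 RPKM), and squamous progenitor genes (0.20, 99.4). With means of members the calls on junction (88.5) and progenitor genes (93.5) were lost, and with upper-quartile scaling the junction median turned to -0.01.

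Lower as groups were hypoxia and glycolysis genes (median -0.22, percentile 0.02), with CA9 at 7.75 against 2.43 RPKM, cell cycle genes (-0.22, 0.02), ribosomal protein genes (-0.19, 0) and respiratory chain genes (-0.20, 0). None of the cell cycle, ribosomal or respiratory chain genes reached a 2-fold difference. The ribosomal protein and respiratory chain lists were included for comparison. Their calls show that a small shift shared by the members is enough for a call. The remaining lists lay within their random range, namely mesenchymal (75.3 percentile), basal keratinocyte (59.2), TGF-beta (88.2), p53 (63.3), unfolded protein (75.8), sterol (44.0) and TSC22 family genes (61.4), although p53 targets passed the range with a filter at 5 RPKM (98.3). HIST1H3C (44.5-fold, 35.6 to 56.3), SCGB1A1, which encodes a secretory protein of airway club cells (20.4-fold, 18.5 to 22.6), MEOX1 (26.8-fold, 19.9 to 36.98) and PADI2 (253-fold, 122 to 632, from 7 reads with empty vector) were among the 12 highest genes. PPIAP22, RPL18AP3, BZW1P2 and RPL15P3, which are pseudogenes, were also among them. SOX2 was 11.9-fold lower (8.98 to 16.2), LYPD1 18.2-fold lower (10.9 to 32.7), galectin-1 (LGALS1) 6.85-fold lower (5.66 to 8.36) and fibronectin (FN1) 6.43-fold lower (5.72 to 7.26). MUC1, CA2, GJA1, RHOBTB3, TUSC3, CALB1 and the small nuclear RNA gene RNVU1-13, which has near-identical copies elsewhere in the genome, were also among the 12 lowest. The long noncoding RNA MIR143HG, left out by its prefix, was at 10.5 RPKM with empty vector and 0 RPKM with S264A. On the scale of log2 RPKM + 1 its drop was larger than that of any of these 12. In all, 359 of 12010 genes were at least 2-fold higher and 99 lower, against 13.0 and 13.4 from counting noise. The higher share was 78.4%, and 61.8% after upper-quartile scaling (241 higher, 149 lower), after which the median gene lay at -0.16, and 61.2% after scaling to an equal sum.

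The third comparison set S264A directly against wild-type THG-1, with fold changes that did not use the empty-vector library, although some list members entered through their level in it. Of the 29 NF-kB targets, 16 were at least 2-fold lower in S264A and none higher, with a median of -1.11 (percentile 0). IL8 was 10.3-fold lower (7.66 to 14.2), IL1A 6.45-fold (4.86 to 8.70), TNFAIP3 5.73-fold (5.02 to 6.57), IL1B 3.83-fold (3.22 to 4.58) and NFKBIA 1.45-fold lower (1.28 to 1.64). PLAU was at 102 against 15.7 RPKM, LIF at 33.4 against 5.32 RPKM and CXCL1 at 25.3 against 4.57 RPKM. TRAF6 had a ratio of 1.15 (0.927 to 1.43). The IL-1 family list had a median of -0.20 (percentile 0.16) with 3 of 27 members at least 2-fold lower (IL1A, IL1B and IL1RL1), and lay inside the random range with a filter at 5 RPKM (22.4). Antimicrobial genes (10 of 18 lower, median -1.08), chemokines and cytokines (6 of 14 lower, median -0.91) and interferon-stimulated genes (13 of 30 lower, 1 higher, median -0.93) were all at percentile 0. The 6 lower chemokine and cytokine genes (CXCL1, CXCL3, IL8, IL23A, LIF and CSF1) were also counted among the 16 lower NF-kB targets. SAA1 was 58.2-fold lower (42.8 to 81.4), SAA2 30.8-fold lower (24.6 to 39.2) and PI3 10.3-fold lower (7.30 to 15.0), while HERC5, an interferon-stimulated gene, was 13.8-fold higher (9.42 to 21.0).

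Mesenchymal genes were lower in S264A than in wild type (7 of 13 at least 2-fold lower, median -1.08, percentile 0), with FN1 at 1.23 against 12.3 RPKM. Hypoxia and glycolysis genes (median -0.37, percentile 0), RAS-MAPK output genes (-0.26, 0.06), proteases (-0.20, 1.6) and ribosomal protein genes (-0.22, 1.5) were lower too. In the quantile-normalised columns the calls on RAS-MAPK output (3.3) and ribosomal protein genes (4.05) were lost, and the call on proteases was lost with a pseudocount of 5 (9.2) and without a filter (5.3). NRF2 antioxidant genes were above their random lists (median 0.20, percentile 99.8), as were suprabasal differentiation genes (0.17, 98.5) and squamous progenitor genes (0.16, 99.02). The suprabasal list was divided, with 4 of 30 members at least 2-fold higher, led by KRT4 (10.8-fold, 9.52 to 12.3), and 4 lower, led by SPRR2D (13.9-fold lower, 8.46 to 24.2), and its call was lost with means of members (87.1) and with a filter at 5 RPKM (95.3). The call on progenitor genes was lost under 5 alternatives, and with a filter at 5 RPKM its median was -0.06. Cell cycle (97.3 percentile), TSC22 family (54.6), basal keratinocyte (16.9), junction (61.8), TGF-beta (21.6), p53 (14.4), unfolded protein (6.2), sterol (5.2) and respiratory chain genes (17.1) lay within their random range. Cell cycle genes passed it with a pseudocount of 5 (97.7), a filter at 5 RPKM (98.4), means of members (99.3), the quantile-normalised columns (98.2) and protein-coding genes alone (97.6). TGF-beta targets lay below it without a filter (0.14) and with means of members (1.73), p53 targets with means of members (2.1) and unfolded protein genes with a pseudocount of 0.1 (1.9).

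The 8 highest genes of S264A against wild type were KRT4, ALPP (11.4-fold, 9.60 to 13.6), H19 (104-fold, 28.5 to 864, from 2 reads with wild type), ALDH3A1, HERC5, SH3BGRL, LGALS7B and CEACAM5. The 8 lowest were SAA1, SAA2, BASP1 (20.7-fold lower, 14.5 to 30.5), CXorf49B, TIMM23B, PI3, SPRR2D and PXDN (33.7-fold lower, 24.5 to 47.6). MIR143HG, left out by its prefix, was at 8.28 RPKM with wild type and 0 RPKM with S264A, a drop close to that of TIMM23B. CXorf49B, TIMM23B and LGALS7B have near-identical copies, and CXorf49B and TIMM23B were at 0 reads in S264A. In all, 187 of 12069 genes were at least 2-fold higher in S264A than in wild type and 269 lower, against 26.9 and 28.2 from counting noise. The higher share was 41.0%, and 60.8% after scaling to an equal sum, after which the median gene lay at 0.13.

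Changes against the empty vector were compared between both THG-1 lines. Among 11624 genes compared in both, 193 were at least 2-fold higher in both lines, where independent lists of 426 and 289 genes would share 10.6 and counting noise alone gave 1.85. For lower genes, 52 were shared, where lists of 185 and 99 genes would share 1.58 and counting noise gave 4.54. Across 12379 genes, which are not independent replicates, the correlation of the log2 fold changes was 0.61, against 0.27 from counting noise through the shared empty-vector library, and the covariance was 0.146 against 0.00504. The empty-vector line is a single library that enters both comparisons and cannot be split, so that part of this excess may come from it. Of the 543 genes at least 2-fold higher with wild-type THG-1, 193 were also at least 2-fold higher with S264A, and 181 were at least 2-fold lower in S264A than in wild type. The median log2 fold change of the 543 genes was 1.36 in wild type and 0.70 in S264A. These genes were selected on the wild-type library, which alone favours a smaller value in S264A.

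**Figure D3:**
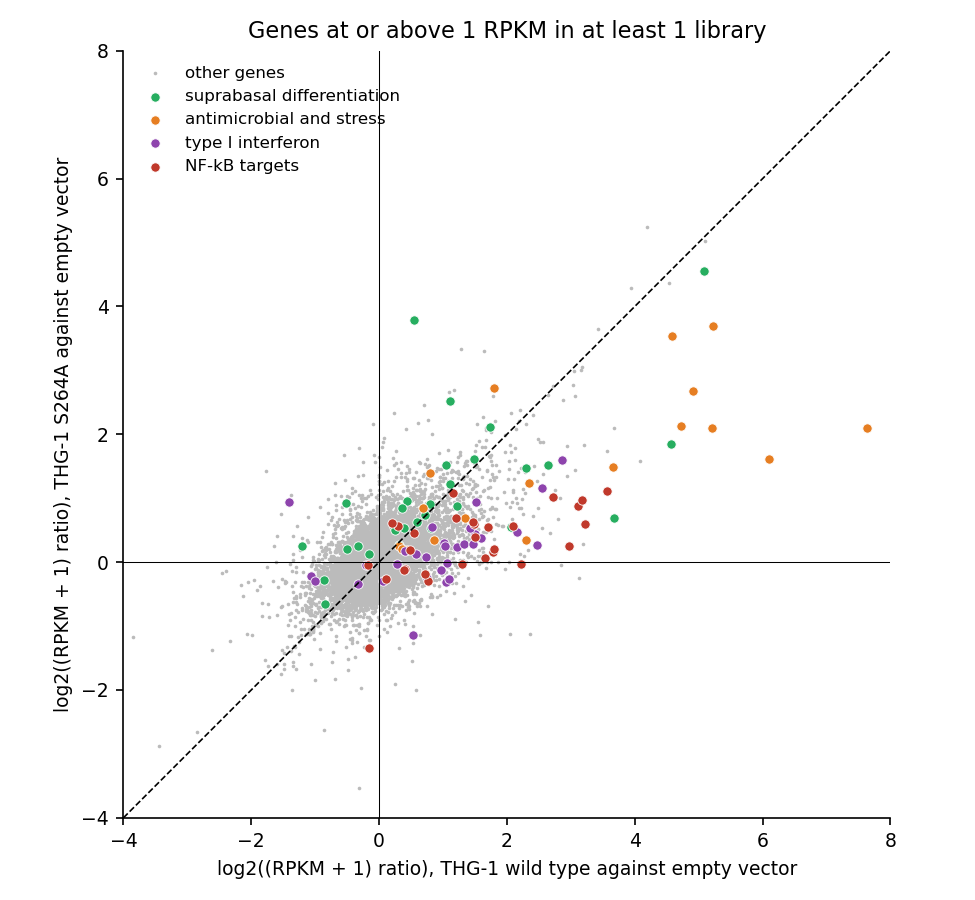
Log2 ratio of RPKM + 1 against the empty-vector line for S264A (vertical axis) and wild-type THG-1 (horizontal axis), 1 point per gene at or above 1 RPKM in at least 1 library, with members of 4 gene lists coloured and a dashed line of equal change. The 18 NF-kB targets and 16 interferon-stimulated genes at least 2-fold higher in wild type lay below the dashed line, and the correlation across 12379 genes was 0.61. These targets and interferon-stimulated genes were selected on the wild-type library, which alone favours a place below the line.

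**Figure D4:**
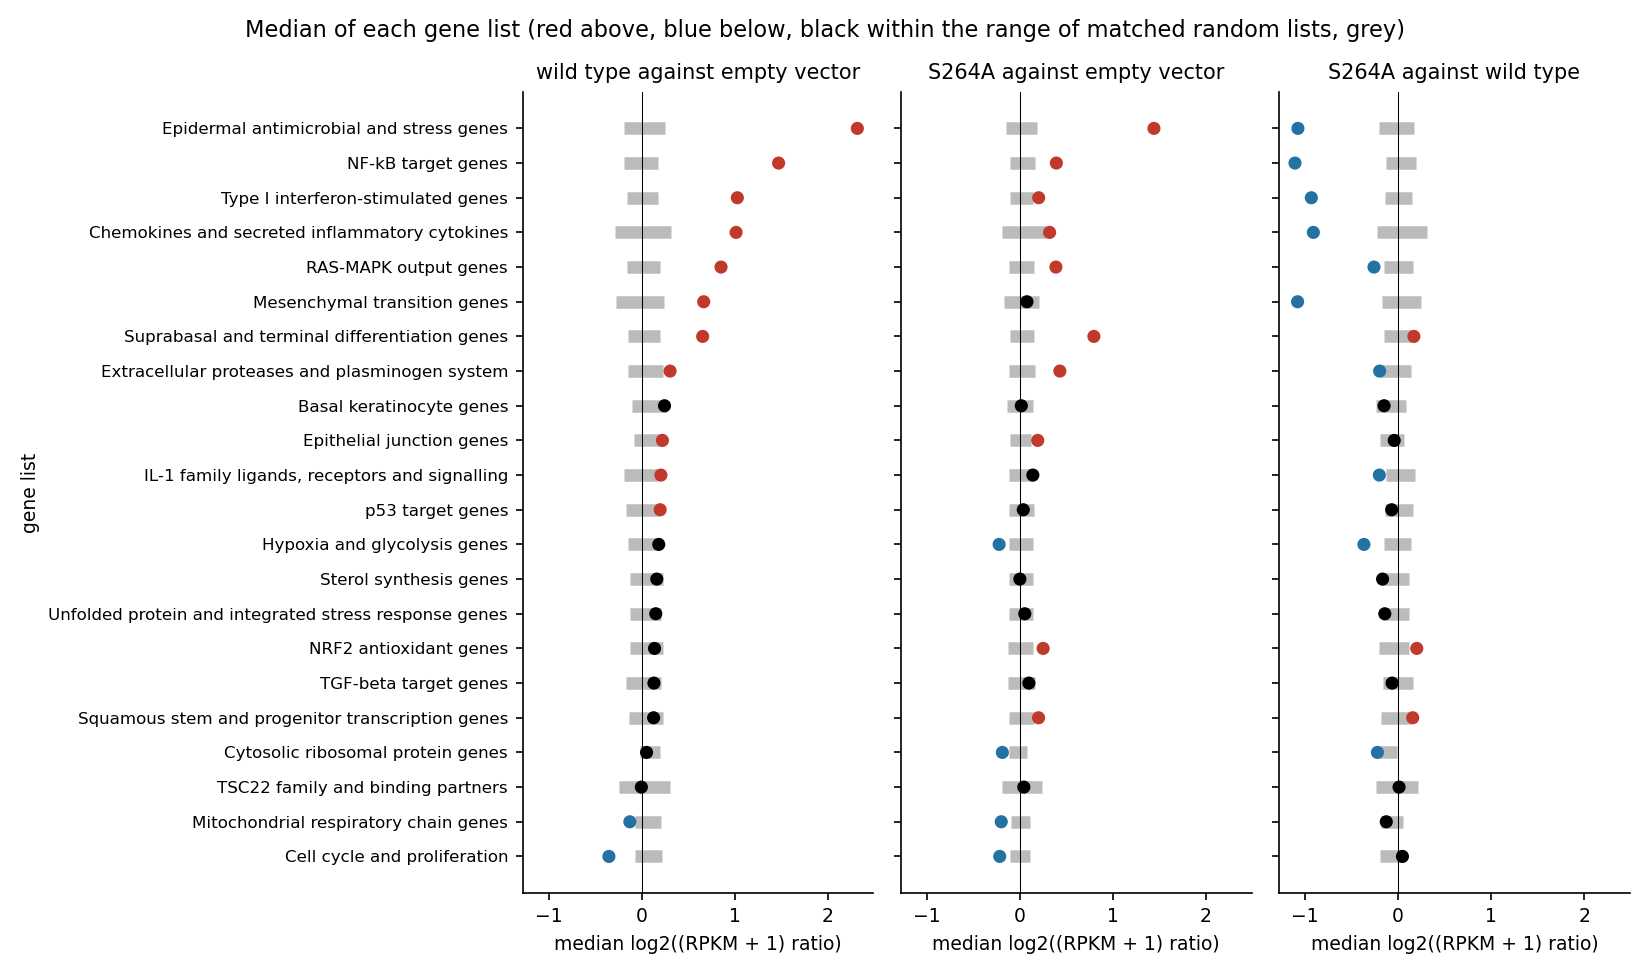
Median log2 ratio of RPKM + 1 of each of the 22 gene lists in the 3 comparisons, with grey bars for the range of 10000 matched random lists outside which a list is called above or below. The NF-kB list had medians of 1.47, 0.39 and -1.11 in wild type against empty vector, S264A against empty vector and S264A against wild type.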

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

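Genes that moved by at least 2-fold in opposite directions in both THG-1 lines, against the same empty-vector library, were singled out by their values. The difference was not tested for any of them because each line was 1 library. BASP1, which encodes a membrane-associated signalling protein, was at 3.50 RPKM with empty vector, 22.1 with wild-type THG-1 and 1.07 with S264A, a difference of -3.48 between the log2 fold changes of S264A and wild type. TIMM23B, which has a near-identical copy, was at 1.18, 8.01 and 0 RPKM (-3.17), and the noncoding transcript AC099522.1 at 3.92, 13.7 and 1.23 RPKM (-2.72). In the other direction, the placental alkaline phosphatase gene ALPP was at 14.7, 3.62 and 41.3 RPKM (3.19), and the aldehyde dehydrogenase gene ALDH3A1 at 9.67, 3.09 and 21.2 RPKM (2.44).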

How the results depend on the processing

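The quantile-normalised columns, the thinned reads and the protein-coding genes were alternatives chosen after seeing the data. Counts of genes stayed within 1.5 times with no filter on low values, equal median ratios, summed repeated symbols, the quantile-normalised columns, thinned reads and protein-coding genes alone. Under the other settings they moved, given here as higher and lower genes for wild type against empty vector, S264A against empty vector and S264A against wild type. A pseudocount of 0.1 gave 869 and 492, 695 and 246, and 509 and 518, and a pseudocount of 5 gave 166 and 18, 85 and 9, and 26 and 63. A filter at 5 RPKM gave 317 and 70, 178 and 26, and 71 and 149. A fold threshold of 1.5 gave 1319 and 806, 1028 and 477, and 802 and 860, and one of 4 gave 103 and 11, 48 and 4, and 13 and 37. Scaling to an equal sum gave 1012 and 1115, 990 and 628, and 1172 and 755. It multiplies RPKM by 3.37 to 3.77, so that the filter and the pseudocount weigh less. Scaling to the same upper quartile moved the lower genes against empty vector, to 313 for wild type and 149 for S264A. The higher genes against empty vector fell from 543 to 365 for wild type and from 359 to 241 for S264A, just within 1.5 times. Genes shared by both THG-1 lines numbered 337 higher and 116 lower with a pseudocount of 0.1, 50 and 4 with one of 5, and 505 and 209 with a threshold of 1.5.

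The NF-kB list kept its call in all 3 comparisons under every alternative run for lists, also without its IL-1 family members. Scaling to an equal sum and summed repeated symbols were not run for lists. The IL-1 family list lost its call for wild type against empty vector with a filter at 5 RPKM (percentile 85.0) and in the quantile-normalised columns (96.2), and for S264A against wild type with that filter (22.4). For S264A against empty vector it gained one with a pseudocount of 5 (99.4), no filter (98.4) and the quantile-normalised columns (97.7). The squamous progenitor list for S264A against wild type lost its call with a filter at 5 RPKM (44.7), and its median changed sign (-0.06). This value lay inside the random range and is counted apart from the lost calls given below. The cause was not tested. Over all lists and alternatives, 683 values kept their call, 26 lost it and 19 gained one, and of the named genes 1411 values kept their side of the 2-fold rule, 91 lost it and 38 gained it, with no reversal. No paired analysis was possible because each group held 1 library. Depth limits genes near the floor, such as IL6 with 2 to 7 reads.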

Other observations

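Keratin genes, chosen here after their values were seen, differed between the lines in distinct ways. The simple epithelial keratins KRT8 and KRT18 were at 126 and 101 RPKM with empty vector, 247 and 246 RPKM with wild-type THG-1 and 126 and 104 RPKM with S264A. The basal keratin KRT14 was at 119, 287 and 382 RPKM, while its partner KRT5 was at 367, 240 and 329 RPKM. KRT16, a keratin of activated epidermis, was at 0.256, 3.37 and 7.27 RPKM and KRT17 at 52.9, 136 and 85.7 RPKM. KRT4 was at 4.003, 6.31 and 68.0 RPKM, whereas KRT13, its usual partner in mucosal epithelium, was at 289, 259 and 317 RPKM. Among transcription factors, SOX2 (16.6, 0.626 and 1.39 RPKM) and SOX9 (2.98, 21.4 and 14.1 RPKM) stood on opposite sides of the empty-vector level in both THG-1 lines. Within the NF-kB list, NFKB1 (6.65, 8.36 and 10.3 RPKM) and TNFAIP2 (22.1, 25.7 and 34.4 RPKM) were highest in S264A, unlike the other members.

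All tests in the following paragraphs except the count of shared 50-mers were chosen after the results were seen.

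NF-kB target genes were higher with wild-type THG-1 and lower again with S264A. Depth did not account for this pattern. After thinning all libraries to the shallowest depth, the list's median of S264A against wild type was -1.08, below its random lists. Both libraries were close in depth (ratio 1.10). The list also kept its call after thinning for wild type against empty vector, where the depths differed 2.52 times. In the quantile-normalised columns the median of S264A against wild type was -1.18, so that the difference remained after that scaling. Its percentile does not test a common scaling factor, which would shift the random lists as well. The S264A line kept 75.7% of the rise in TSC22D4 transcript, and a response proportional to it would give a median of -0.24, whereas 24 of the 29 members lay below that prediction, by a median log2 difference of -0.88 (quartiles -1.35 and -0.36). A response that is not proportional, and the level of THG-1 protein, were not tested. The S264A change itself, which the design sets, may underlie the difference and was not tested apart from the line, since a chance difference between independently made lines cannot be told apart from it with 1 library per group.

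Some genes were listed at 0 in the empty-vector library, the deepest, and were present in both THG-1 libraries. With at least 50 reads expected from the other libraries, 11 genes were at 0 with empty vector, 0 genes with wild-type THG-1 and 2 genes (MIR143HG and TIMM23B) with S264A. Expected reads were scaled to the depth of the library at 0, so that a lower level sufficed for the deeper empty-vector library. These counts are therefore not on equal terms. None of 83 ribosomal protein and respiratory chain genes was at 0 in any library. They were not matched in level to the genes at 0, so that their presence says little about genes with few reads. MIR143HG, a long noncoding RNA, had 5992 reads with empty vector (10.5 RPKM) and 1870 with wild-type THG-1 (8.28 RPKM). It was not among the transcripts searched for shared sequence, and its absence with S264A was not explained. For the 11 genes at 0 with empty vector a lower depth is excluded, as that library was 2.52 times as deep as the wild-type library. Of 10 genes found in the transcript set, 4 (HSD17B2, IGF2BP1, SPIN3 and SYNDIG1) shared under 10% of their 50-base words with other genes. For these 4, exact sharing over most of the gene was not seen. Copies with mismatches or outside the transcript set, and where in the gene the reads lay, were not examined. Shared reads are therefore not excluded for them. The 6 others shared at least 50%, and for PPIAP22, BZW1P2 and RPL15P3 such sharing cannot be told apart from a real difference, because the copies PPIA (180, 125 and 132 RPKM), BZW1 (33.7, 30.3 and 35.5) and RPL15 (54.4, 46.7 and 45.6) differed between the THG-1 libraries alone by more reads than were missing. HNRNPA1 (92.9, 96.4 and 95.4 RPKM) differed there by 157 reads, against 204 missing from HNRNPA1P48. Its reads with empty vector differed from the mean of the THG-1 libraries at that depth by -489. This difference is larger than the missing reads, so that an excess of that size could not be seen and sharing stays open. No copy was examined for AL359955.1 and AC005523.2. A difference of the empty-vector line that has nothing to do with THG-1 is a candidate explanation that stays open with 1 library per group, and it would enter both comparisons against that line.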
